A study of Mus musculus with 6 samples.

How the data were processed

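Gene expression was measured with Affymetrix arrays in colon epithelium of male C57BL/6J mice aged 8 weeks, 3 arrays from wild type mice and 3 from mice in which Sel1l was deleted in intestinal epithelial cells. Per the labels' protocols, exon 6 of Sel1l was flanked by loxP sites and removed by a Cre recombinase under the villin promoter, and labelled cDNA was made from total RNA of Bioanalyzer-checked quality. The deposited values are on a log2 scale and were made with RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of each probe set. The log2 scale was read from the range of the deposited values, and the RMA software, its version, the probe set definition and the genome build are not given in the sources used here. The array medians of the deposited log2 values lay between 6.32 and 6.36, and no further normalization was applied.

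Of 35556 probe sets, 21789 named 1 gene in the platform annotation, 1621 named several genes and 12146 had no gene in that table. Symbols were updated through the RefSeq gene table of assembly GRCm38.p6, used here for names and gene neighbourhood only, by gene identifier for 21698 probe sets and by accession for 3, and 88 kept the annotation's symbol. Probe sets with several genes or none were left out of the gene test, and control probe sets are not marked in the tables used here. Each gene was represented by the probe set with the highest mean over all 6 arrays, which gave 19936 genes, 1001 of which had more than 1 probe set. No filter on dim probe sets was applied.

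Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term), with two-sided tests and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. Changes are given as knockout minus wild type on the log2 scale with the moderated standard error (SE), and levels as mean ± SD of 3 arrays. The level of Sel1l was also compared with an exact two-sided permutation test, for which 3 arrays against 3 cannot give a p below 0.1. Tables were joined and plotted in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The labels do not say that each array stands for a separate mouse, so the p-values measure the spread between these arrays. The number of arrays limits the precision. Litter, hybridisation batch and scan date were not used here, so no batch could be tested.

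Before the data were examined, 38 gene lists with 687 memberships were fixed from textbook knowledge, of which 638 were measured. Lists of at least 5 measured members, 37 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with the remaining genes, and adjusted over the lists. The erythroid list had only 3 measured members and was not tested. Camera with an estimated correlation and limma's fry, which tests whether the members move one way on balance, were run beside it. Members were counted as called over all genes and also adjusted over the list alone. Some genes are in more than 1 list, among them Derl3 (degradation and plasma cells), Ern2 and Creb3l1 (stress sensors and goblet cells) and Saa1 (absorptive cells and inflammation).

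The named genes follow a rule fixed at the same time. It takes Sel1l, Syvn1, Ern1, Ern2, Xbp1, Hspa5, Dnajb9 and Ddit3 in every case. It adds the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, leaving out predicted genes. It also adds up to 4 members with the smallest p from each list that passed or had a member called, over all genes or over the list alone. Genes outside the rule were named after their values were seen.

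The alternatives were a replicate number block, quantile normalization, median centring, leaving out the dimmest 25% or 50% of genes, an intensity trend or a robust prior in eBayes, array weights, the mean of a gene's probe sets, each array left out in turn, a test without moderation, a threshold of 1.5-fold, the other list tests and camera on ranks. A test of all probe sets together and 7 further gene lists were chosen after seeing the data. The gene test was tested on simulated data with 200 changed genes among 19936. It called 86% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1, and 4.12% of its calls had no true change. The simulated noise was normal and independent between genes, with the moderated SD of each gene. In the real arrays genes were correlated, with an estimate of 0.76 in the interferon response list, so these rates may not carry over.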

Results

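Sel1L is the adaptor of the ubiquitin ligase Hrd1, encoded by Syvn1, in endoplasmic reticulum (ER)-associated degradation, the pathway that removes misfolded proteins from the ER. The series asks about IRE1α, the ER stress sensor encoded by Ern1, as a protein that this pathway degrades, and compares transcripts of colon epithelium with and without Sel1L. Levels are RMA log2 values from 3 wild type and 3 knockout arrays. Correlations between arrays across genes, which are not independent replicates, ran from 0.993 to 0.997. The SD of the difference between arrays of a genotype was 0.167 to 0.194, so none was a copy of another. The first principal component held 38.3% of the variance and placed the 3 wild type arrays on one side and the 3 knockout arrays on the other.

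Sel1l itself was lower in the knockout, at 8.81 ± 0.22 against 9.55 ± 0.11 in wild type (SD, n = 3 each), a change of -0.74 ± 0.11 (SE) with limma's adjusted p = 0.018. Each knockout array lay below each wild type array, and the exact permutation p was 0.1, the smallest this design allows. The wild type arrays read 9.45, 9.67 and 9.54 and the knockout arrays 8.70, 9.06 and 8.66. Only exon 6 was removed, and the probe set was not mapped to that exon here, so its remaining signal does not measure how complete the deletion was. The adjusted p rose to 0.055, 0.077, 0.087 and 0.060 without wild type array 1, wild type array 2, knockout array 1 and knockout array 3.

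Syvn1 rose by 0.77 ± 0.094 (adjusted p = 0.0099). Hspa5, which encodes the major ER chaperone BiP, rose by 0.85 ± 0.087 (adjusted p = 0.0064), and Ddit3, which encodes the stress transcription factor CHOP, rose by 0.79 ± 0.098 (adjusted p = 0.010). Dnajb9, a BiP cochaperone, rose by 0.66 ± 0.097 (adjusted p = 0.017), a call that ended without wild type array 1 or knockout array 1, where the adjusted p reached 0.073. Xbp1, whose mRNA is spliced by IRE1α, differed by 0.25 ± 0.061 and was not called (adjusted p = 0.10). The array does not separate spliced from unspliced Xbp1. The transcripts of Ern1 and of Ern2, its epithelial paralog, did not pass the test, with -0.015 ± 0.086 (adjusted p = 0.96) and -0.044 ± 0.074 (adjusted p = 0.86). IRE1α protein was not measured here.

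**Figure D1:**
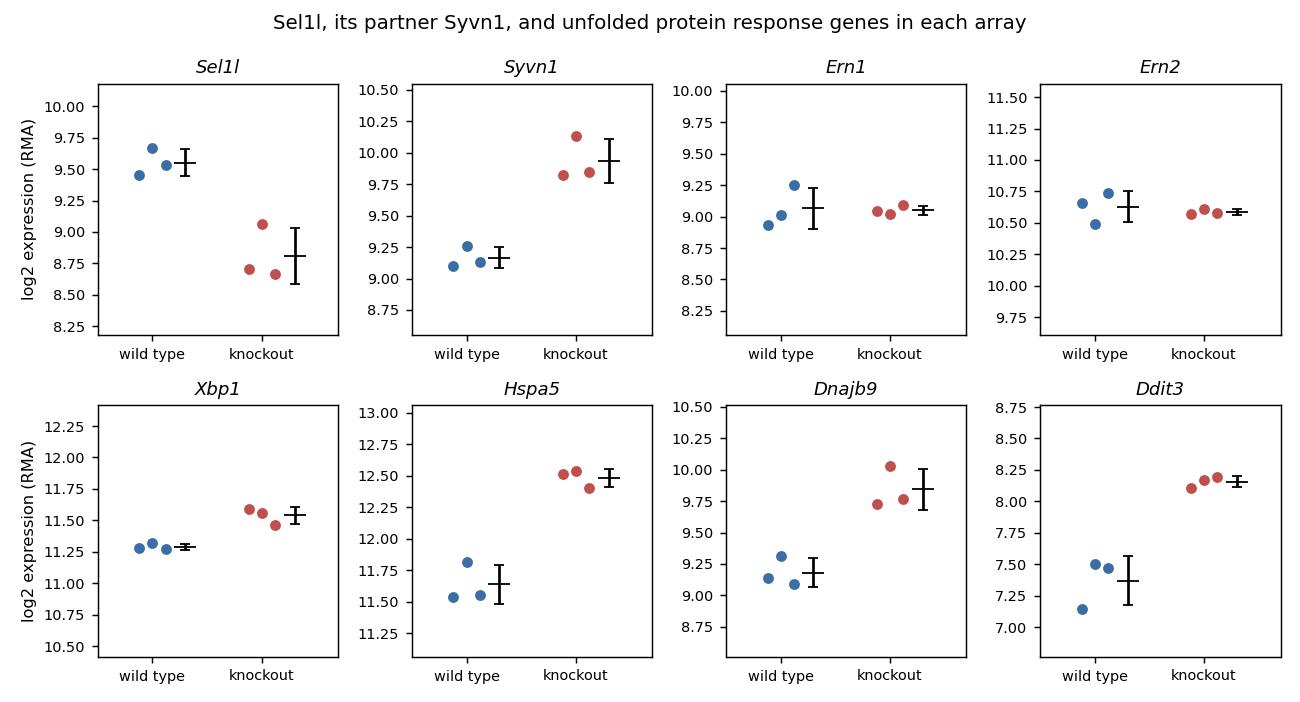
Log2 expression (RMA) of Sel1l, Syvn1 and 6 unfolded protein response genes in each of 3 wild type (blue) and 3 knockout (red) arrays, with mean and SD beside the points and a vertical axis of the same length in every panel. Sel1l was lower in all 3 knockout arrays, Syvn1, Hspa5, Dnajb9 and Ddit3 were higher, Xbp1 was not called, and Ern1 and Ern2 overlapped between genotypes.

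Over all 19936 genes, limma called 325, with 183 higher and 142 lower in the knockout, and 118 of them changed at least 1.5-fold, 59 in each direction. The groups did not overlap in any called gene, nor in 19.4% of all genes, against 10% by chance. The largest rises were those of Aldh1l2, a mitochondrial folate enzyme (2.65 ± 0.14, adjusted p = 0.00034), and Derl3, a Derlin of the degradation pathway (2.49 ± 0.17, adjusted p = 0.0013). Slc7a11, the cystine transporter, rose by 2.03 ± 0.34 (adjusted p = 0.028), and Mt1, a metallothionein, by 1.87 ± 0.058 (adjusted p = 1.0e-05), to 12.21 ± 0.024 from 10.35 ± 0.051. Nucb2 (1.43), Pck2 (1.38), Asns (1.22), Psat1 (1.22), Sdf2l1 (1.17) and Rgs2 (1.13) completed the 10 largest rises. The largest falls were those of the class II antigen presentation genes H2-Aa (-2.84 ± 0.38), Cd74 (-2.48 ± 0.33) and H2-Ab1 (-2.20 ± 0.32), with adjusted p values of 0.012, 0.012 and 0.017. Meg3, an imprinted long noncoding RNA, fell by 1.33 ± 0.14 on the log2 scale (adjusted p = 0.0065), and Ido1, a tryptophan-degrading enzyme induced by interferon, by 1.33 ± 0.22 (adjusted p = 0.025). H2-Eb1 (-1.28), Cyp2d12 (-1.24), Upp1 (-1.17), Stom (-1.10) and Ly6g (-1.09) followed. Ly6g, Cyp2d12 and the H2 genes belong to families of similar genes, so their probe sets may read related transcripts.

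Of the 50 called genes named by the rule besides Sel1l, 24 stayed called with each array left out and 4 lost the call every time. Slc7a11 kept it only without wild type array 3 (adjusted p = 0.00093), with an adjusted p of up to 0.11 when other arrays were left out, and its wild type levels were 6.02, 6.48 and 7.63. Ido1, Cyp2d12, Upp1 and Ly6g kept the call in 2, 2, 1 and 2 of these 6 fits, with adjusted p up to 0.091, 0.092, 0.14 and 0.064. The count of called genes fell to 96 and 95 without wild type arrays 1 and 2, and to 69, 120 and 187 without knockout arrays 1, 2 and 3.

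**Figure D2:**
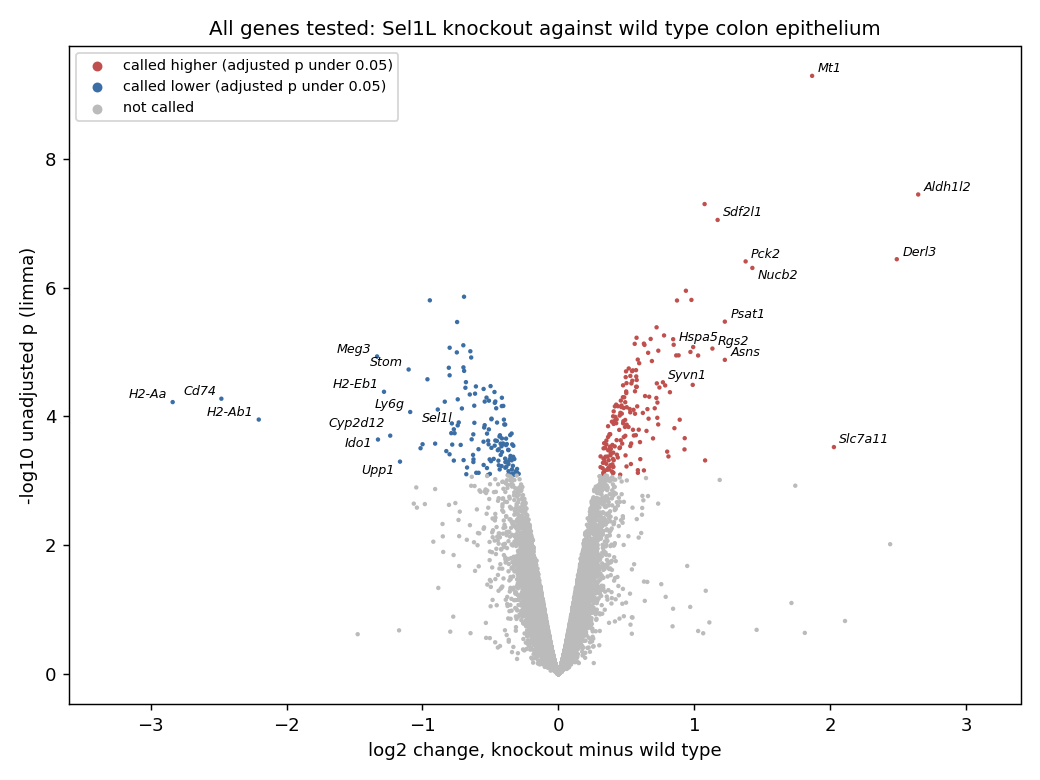
Log2 change (knockout minus wild type, horizontal) against -log10 of limma's unadjusted p (vertical) for 19936 genes, with 183 called higher in red and 142 called lower in blue. Aldh1l2 (2.65) and Derl3 (2.49) lie furthest right, and H2-Aa (-2.84) and Cd74 (-2.48) furthest left.

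Lists of unfolded protein response genes shifted up at the preset correlation of camera, though not every member was called. Among targets of the PERK-ATF4-CHOP branch, which adjusts translation and amino acid supply, 17 of 30 rose and none fell, with a median change of 0.57 and 27 higher when adjusted over the list alone (camera adjusted p = 7.0e-31, and adjusted p = 0.16 with an estimated correlation). Besides Aldh1l2, Psat1 and Asns, they included Eif4ebp1 (0.87 ± 0.093), Atf5 (0.84 ± 0.084) and Phgdh (0.57 ± 0.068), a serine synthesis enzyme. Wild type array 3 had the highest mean deviation of its group over this list (0.20, against -0.14 and -0.07), below the knockout arrays at 0.73 to 0.75. Chac1, a glutathione-degrading enzyme outside the naming rule, differed by 1.74 ± 0.36 without being called (adjusted p = 0.062). Among ER chaperones and folding enzymes 16 of 24 rose, 22 adjusted over the list alone, with a median of 0.54 (camera adjusted p = 1.8e-30, and adjusted p = 0.16 with an estimated correlation). Sdf2l1 rose by 1.17 ± 0.069, Pdia6, a disulfide isomerase, by 0.94 ± 0.075, Hyou1, an ER chaperone, by 0.87 ± 0.073, and Hsp90b1, which encodes GRP94, by 0.68 ± 0.068, and these 4 calls held with each array left out.

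In the XBP1s-dependent secretory pathway 11 of 37 genes rose, 30 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 3.1e-23, and adjusted p = 0.25 with an estimated correlation). Kdelr3, a receptor for escaped ER proteins, rose by 0.88 ± 0.095, Serp1 by 0.69 ± 0.076, the vesicle coat gene Sec24d by 0.63 ± 0.064 and the translocon gene Sec61b by 0.50 ± 0.059, the last with adjusted p = 0.052 without knockout array 1. In ER-associated degradation 4 of 30 rose, 14 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 7.6e-09, and adjusted p = 0.25 with an estimated correlation). They were Derl3, Syvn1, Herpud1 (0.73 ± 0.11) and Edem2 (0.49 ± 0.066), and the last 2 lost the call without wild type array 1, wild type array 2, knockout array 1 or knockout array 2, with adjusted p up to 0.078 and 0.066. The list of ER stress sensors shifted up, with 3 of 11 called and 5 adjusted over the list alone, at a median of 0.070 (camera adjusted p = 0.0013, adjusted p = 0.25 with an estimated correlation, and adjusted p = 0.084 with camera on ranks), and of 0.11 without wild type array 2. The 3 were Creb3l2 (0.74 ± 0.093), Atf4 (0.54 ± 0.066) and Atf6 (0.46 ± 0.061). Atf4 and Creb3l2 lost the call without knockout array 1, and Atf6 without wild type arrays 1 or 2 or knockout arrays 1 or 2, with adjusted p up to 0.063.

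Transcripts that IRE1α can cleave, known as RIDD substrates, shifted down with a median of -0.14 (camera adjusted p = 0.00025, and adjusted p = 0.16 with an estimated correlation). Of 9 measured, 1 fell, Tapbp (-0.55 ± 0.070, adjusted p = 0.010), which encodes tapasin of the antigen-loading complex, and 3 were lower when adjusted over the list alone. Bloc1s1, a much used marker of this cleavage, differed by -0.24 ± 0.059 and was not called (adjusted p = 0.11), nor were Pdgfrb (-0.24) and Sparc (-0.33).

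The antigen presentation list shifted down. Of 13 measured, 8 fell and 11 were lower adjusted over the list alone, with a median of -0.46 (camera adjusted p = 6.8e-18, and adjusted p = 0.16 with an estimated correlation). H2-Aa was 7.15-fold and Cd74, the invariant chain, 5.58-fold higher in wild type. H2-DMa, a class II peptide-loading gene, fell by 0.89 ± 0.12 on the log2 scale, and the class I pathway genes B2m (-0.40) and Psmb8 (-0.63) were also called. The class II transactivator gene Ciita differed by -0.14 and was not called (adjusted p = 0.53). The calls of H2-Aa, Cd74 and H2-DMa ended without wild type array 1, wild type array 2 or knockout array 1, that of H2-Ab1 also without knockout array 3, and that of H2-Eb1 without wild type array 1 or knockout array 1. The adjusted p then reached at most 0.073. The interferon response list shifted down with a median of -0.34 (camera adjusted p = 6.9e-10, and adjusted p = 0.39 with an estimated correlation), and of -0.20 without wild type array 3. The mean deviations of the wild type arrays were -0.078, -0.29 and 0.36, the second close to the knockout arrays at -0.41, -0.35 and -0.30. Of its 20 genes, 1 fell, the transcription factor gene Irf1 (-0.49 ± 0.072, adjusted p = 0.017), and 2 adjusted over the list alone, while Iigp1 (-0.85 ± 0.27), Ifit2 (-0.59 ± 0.18) and Ifit3 (-0.48 ± 0.12) were not called over all genes. A second Irf1 probe set gave -0.093, and the mean of both was not called (adjusted p = 0.10). Irf1 was also not called without wild type arrays 1 or 2 or knockout arrays 1 or 2, with adjusted p up to 0.073.

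Genes of absorptive colonocytes, the cells that take up salt and water, shifted down with a median of -0.26 (camera adjusted p = 9.7e-14, and adjusted p = 0.25 with an estimated correlation). Of 20, 3 fell and 12 were lower adjusted over the list alone. They were the proton pump gene Atp12a (-0.81 ± 0.092), the water channel gene Aqp8 (-0.80 ± 0.14) and the sodium channel gene Scnn1b (-0.64 ± 0.10). Car4, a carbonic anhydrase, differed by -0.52 ± 0.10 (adjusted p = 0.051), whereas Car1 and Krt20 differed by 0.0058 and -0.070. Atp12a kept its call with each array left out. Aqp8 kept it only without wild type array 3 or knockout array 3 and Scnn1b only without knockout array 2, with adjusted p up to 0.13 and 0.11. The enteroendocrine list shifted down with a median of -0.077 (camera adjusted p = 0.0016, adjusted p = 0.48 with an estimated correlation, and adjusted p = 0.051 without wild type array 1). The median ran from -0.16 to -0.035 with an array left out, and the mean deviations overlapped, at 0.16, -0.048 and -0.11 in wild type against -0.13, -0.071 and -0.25 in the knockout. Of its 18 genes, 1 fell, the peptide hormone gene Pyy (-0.49 ± 0.072), and 2 adjusted over the list alone, and Pyy kept its call only without wild type array 3, with adjusted p up to 0.068 otherwise. Insl5 (-0.60 ± 0.14) and Chga (-0.44 ± 0.17) were not called. The tuft cell list shifted up with a median of 0.12 and no gene called (camera adjusted p = 0.0058, and adjusted p = 0.39 with an estimated correlation), and 4 of its 13 genes had an unadjusted p under 0.05, among them Dclk1 (0.23).

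Cholesterol synthesis genes shifted down with a median of -0.17 (camera adjusted p = 1.7e-09, and adjusted p = 0.25 with an estimated correlation). Of 18, 1 fell, Cyp51 (-0.33 ± 0.064, adjusted p = 0.0498), which lost the call with each array left out, and 9 were lower adjusted over the list alone, with Idi1 (-0.30) and Dhcr7 (-0.24) next. Tight junction and adhesion genes shifted down with a median of -0.14 (camera adjusted p = 8.5e-05, and adjusted p = 0.25 with an estimated correlation), with no gene called of 15, 6 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Cdh1, which encodes E-cadherin, and Epcam each differed by -0.23 ± 0.058. In the list of epithelial antimicrobial and oxidase genes the median was -0.18 (camera adjusted p = 0.019, and adjusted p = 0.39 with an estimated correlation). Its camera call also ended without wild type array 2 or 3 (adjusted p = 0.14 and 0.12, with a median of -0.092 without array 2), on ranks (adjusted p = 0.16) and without the dimmest 50% of genes (adjusted p = 0.078). The mean change was -0.041, with 6 members positive and 10 negative. Mean deviations overlapped, at -0.16, 0.13 and 0.033 in wild type against -0.011, -0.016 and -0.095 in the knockout. The 2 called genes of 16, 4 adjusted over the list alone, were the oxidase genes Nox1 (-0.46 ± 0.076) and Duox2 (-0.44 ± 0.081), both lost with each array left out. Antimicrobial genes such as Ang4 (0.95) and Reg3b (-0.53) were not called.

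Immediate early genes shifted up with a median of 0.072, with 1 of 16 called, Nr4a1 (0.71 ± 0.098), and 3 adjusted over the list alone (camera adjusted p = 0.0055, adjusted p = 0.28 with an estimated correlation, and adjusted p = 0.080 without wild type array 3). The median ran from 0.042 to 0.12 with an array left out. Nr4a1 lost its call without wild type arrays 1 or 2 or knockout arrays 1 or 2, with adjusted p up to 0.061. The cell cycle list had a median of -0.065 with no gene called of 27 and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.012, and adjusted p = 0.78 with an estimated correlation). It rested on knockout array 2, without which the median was 0.030 (adjusted p = 0.96), against -0.16 without knockout array 1.

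Of the 37 lists, 16 passed camera at the preset correlation, 7 up and 9 down. None passed with an estimated correlation, where 5 had an unadjusted p under 0.05, and 9 passed fry, 5 up and 4 down. The fry calls were the unfolded protein response lists, antigen presentation, cholesterol synthesis, tight junction and RIDD substrates.

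Lists of other cells that the preparation could hold did not pass camera. The adjusted p was 0.41 for macrophages and dendritic cells, 0.78 for neutrophils, 0.78 for T cells and intraepithelial lymphocytes, 0.82 for B and plasma cells, 0.54 for fibroblasts, 0.82 for smooth muscle, 0.78 for endothelium and 0.78 for enteric nerve and glia. Few markers lay above the array median of 6.34, such as 1 of 10 for enteric nerve and glia and 5 of 12 for fibroblasts. This was not counted for neutrophils. A smaller number of such cells could thus hardly show in these lists. The only called genes in them were Derl3, which is also in the degradation list, and Ly6g, while the neutrophil genes S100a8 and S100a9 both differed by 0.21 and were not called. Crypt stem cells (0.11), goblet cells (0.11) and small intestine enterocytes and Paneth cells (0.55) did not pass either. Within the small intestine list Rbp2 fell by 0.33 ± 0.056 on the log2 scale (lost with each array left out), and Pnliprp2 differed by 2.44 ± 0.73 without being called, with wild type levels of 6.25, 7.34 and 9.77. Goblet cell markers had 5 genes higher and 1 lower adjusted over the list alone, among them Spdef (0.28 ± 0.072) and Muc4 (-0.44 ± 0.091), and Muc2 differed by -0.044.

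Further lists gave camera adjusted p values of 0.16 for NF-kB and acute inflammation, 0.23 for the circadian clock, 0.25 for C57BL/6 substrain variants, 0.28 for autophagy, 0.49 for NRF2 targets, 0.51 for p53 and apoptosis, 0.59 for oxidative phosphorylation, 0.61 for cytosolic heat shock, 0.61 for proteasome subunits and 0.82 for fatty acid oxidation and ketogenesis. None of their genes was called over all genes. Adjusted over the list alone, autophagy had 1 gene higher, Sqstm1 (0.31 ± 0.067), NRF2 targets had 2 higher and 1 lower, Hmox1 (0.40 ± 0.084), Me1 (0.73 ± 0.17) and Gsta3 (-0.40 ± 0.12), and the clock list had 1 lower, Arntl (-0.35 ± 0.070). Median, mean and test differed in sign for macrophages, NRF2 targets, small intestine, neutrophils, T cells, B cells and smooth muscle.

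**Figure D3:**
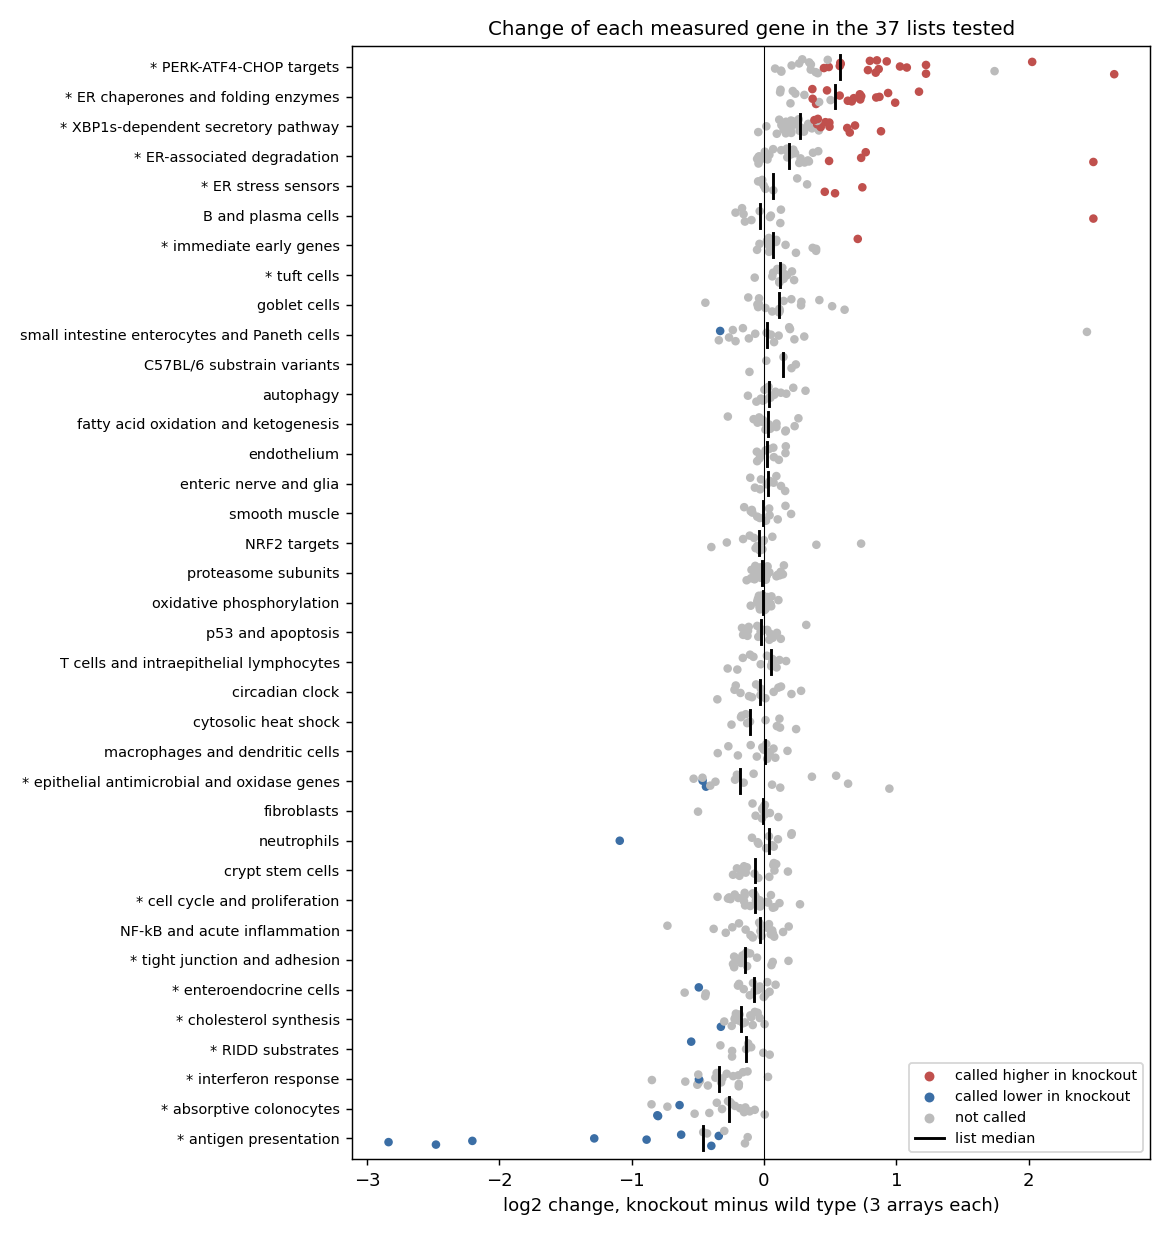
Log2 change (knockout minus wild type) of each measured gene in the 37 lists, 1 point per gene, with the list median as a black line and lists that passed camera at the preset correlation marked with an asterisk. Red points were called higher, blue points lower and grey points were not called, and the unfolded protein response lists have medians above 0, with antigen presentation furthest left.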

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

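All tests in this part were chosen after the results were seen, except the splits of the arrays and the test of colon region, whose gene list was added after the first results but before its own values were read. Outside the named genes, 23 probe sets without a gene in the annotation were higher in the knockout than in the wild type arrays, the controls of this design, in a limma fit of all probe sets, and 30 were lower. That fit called 53 of the 12146 probe sets without a gene, and 96 of the 21789 that named 1 gene. Probe set 10338357 read 3.83 against 2.94 and probe set 10343438 read 4.82 against 4.13, whereas 10412520 read 5.23 against 5.89 and 10417421 read 5.36 against 6.17 (adjusted p = 0.027 each). The means of 10338357 and 10343438 lay below the lower quartiles of the arrays (4.86 to 4.91). Control probe sets are not marked, so the unnamed probe sets may include some.

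The count of 325 called genes was set against other groupings of the arrays. Of the 10 splits of the 6 arrays, 1, the real one, gave a count as large, and the highest of the others was 0 by limma (1275 genes at an unadjusted p under 0.05 in the highest other, against 2659). These splits are too few for a share under 0.05.

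Class II genes H2-Aa, Cd74, H2-Ab1, H2-Eb1 and H2-DMa changed by a median of -2.20 (log2) in the knockout. Signal shared between H2 paralogs as the whole cause is argued against by the 7 single-copy genes of the list, whose median was -0.43 with a mean of -0.72 ± 0.11 (SE). They include Cd74 (-2.48), itself 1 of these class II genes, and the others are not class II genes. How far the H2 probe sets share signal was not tested. Of 15 T cell and general leukocyte markers, 4 lay above the array median of 6.34 (Ccl5, Cd3e, Ptprc and Thy1). Their median was -0.042 ± 0.074, which argues against a loss of leukocytes of every kind as large as the class II fall, but only for these markers. A smaller loss could hardly show in so few. Fewer macrophages, dendritic cells or B cells cannot be told apart from a change in the epithelium, because only 2 of their markers lay above that median, Cd14 and Cd68, at a median of -0.15, with Derl3 (2.49) left out as a degradation gene. A lower interferon response may take part, since the interferon list shifted by -0.35 ± 0.19 (SE). Against it, wild type array 3 had the highest interferon mean (0.36) and the lowest class II mean (-0.39) of its group. Among the knockout arrays, array 1 was lowest in both (-0.41 and -2.29). Array 3 was highest there for interferon (-0.30) and array 2 for class II (-1.35). With 3 arrays per genotype, a part of the interferon response stays open. An effect of the Sel1L deletion itself on epithelial class II genes also stays open.

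Meg3 fell by 1.33 on the log2 scale, and its imprinted neighbours Rian (-0.39, adjusted p = 0.037) and Dlk1 (-1.05, adjusted p = 0.064) lay in the same direction. Rtl1 (0.026) and Dio3 (0.034) did not. In wild type they read 6.24 and 4.65, below the array median of 6.34, where a fall may not show. Rian also lay below it, at 5.08. The list of these 5 genes passed camera (adjusted p = 0.00033) but not with an estimated correlation (adjusted p = 0.088). It was chosen after the fall of Meg3 was seen and includes Meg3. Its camera result is therefore not separate support for a fall of the cluster. Over 17 imprinted genes of other loci the median was 0.10 ± 0.076 (SE). Many of them, such as Zdbf2 (3.82) and Ndn (4.40), lay below the array median of 6.34 in wild type, where a fall may not show. Those above it in wild type were Mcts2 (0.20), Impact (0.13), Airn (0.17), Igf2r (0.11) and Phlda2 (0.12). They argue against a general fall of imprinted genes, but only for these genes. Fibroblasts, smooth muscle and enteroendocrine cells had 5, 3 and 9 markers above the array median, with median changes no lower than -0.19 ± 0.088. For these markers, this argues against a loss of such cells as large as the fall of Meg3. A smaller loss could hardly show in so few markers, and the enteroendocrine list was itself called lower by camera (adjusted p = 0.0016). Whether fewer such cells take part in the fall of the cluster stays open. Nerve cells and endothelium had 1 and 2 markers above the array median, with a lowest median of 0.073, too few to tell. Sel1l and this cluster lie on the same chromosome in assembly GRCm38.p6, and 0 of the 104 genes measured between Sel1l and Dlk1 were called by limma (12 at an unadjusted p under 0.05), against 1.64% elsewhere (Fisher's exact p = 0.42), a difference too small to decide on a chromosome segment carried along with the allele. An effect of the deletion on the cluster was not tested.

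Absorptive colonocyte genes shifted by a mean of -0.36. The change of 3 of the 20 members differed from the list mean (adjusted p = 0.020 each), with Atp12a lower and Krt20 and Car1 higher. This argues against a lower share of these cells as the whole cause, if a lower share lowers each member alike. Whether each member is read from these cells alone was not tested. With 19 of the 20 members negative, a lower share may take part. A different stretch of colon may have been sampled, since the distal list of HOX genes was called lower by camera (adjusted p = 0.039) with 8 of 10 members negative, but not with an estimated correlation (adjusted p = 0.34), and its mean shift of -0.09 ± 0.087 (SE) lay within 2 SE of 0 and also within 2 SE of 50% of the absorptive shift, which leaves this open. A change of absorptive genes within the knockout cells stays open as a hypothesis.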

How the results depend on the processing

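The 7 added lists and the test of all probe sets together were chosen after seeing the data, and the other settings of this part before. The replicate numbers were not taken as pairs, since same-numbered arrays had correlations of deviations of -0.10, 0.15 and 0.15. Wild type array 1 correlated best with knockout array 3, and wild type arrays 2 and 3 with knockout arrays 2 and 3. With the number as a replicate block 217 genes were called (117 higher and 100 lower, 200 of them shared with the 325). The count was 598 (324 higher, 274 lower) without the dimmest 50% of genes, where fewer genes were tested, 614 (325 and 289) with an intensity trend, 118 (59 and 59) at 1.5-fold, and 4 (2 and 2) without moderation, with 2392 genes at an unadjusted p under 0.05. All probe sets tested together gave 161 called probe sets (91 and 70), of which 96 named 1 gene (66 and 30), 12 several genes and 53 none. The cause of the rise with a trend was not tested. With each array left out, the count ran from 69 to 303, with 46 to 190 higher and 23 to 113 lower, where fewer arrays enter the fit. The other settings called 318 to 449 genes.

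Sel1l kept its direction under all settings, from -0.87 to -0.67 with an array left out, and its adjusted p was 0.20 without moderation, where it changed by -0.74. No list was called by camera with an estimated correlation (0 up and 0 down, 5 at an unadjusted p under 0.05), and 9 by fry (5 up, 4 down), against 16 (7 and 9). The other list settings gave 14 to 18. Robust eBayes was not run for lists. Of 620 comparisons of 37 lists, 579 kept the side of the threshold, with 31 losing and 9 gaining the call. A turn of camera's direction was counted only for lists called in the main test or in that setting, which gave 1. Lists called in neither were not required to keep their direction. The cell cycle list ran from -0.16 to 0.030 with an array left out, turning without knockout array 2, and the cause was not tested.

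For 112 named genes besides Sel1l, 1541 of 1771 comparisons kept direction and side of the threshold, 160 lost the call and 67 gained it. Those that turned were not called in any setting reported here: with an array left out Ern1 ran from -0.080 to 0.078 (0.078 without wild type array 3, 0.0015 without knockout array 2) and Ern2 from -0.11 to 0.0080 (0.0080 without wild type array 3). Apart from the block, arrays left out and the test without moderation, calls were lost by Cyp51 (median centring, robust eBayes, array weights), Slc7a11 (robust eBayes) and Irf1 (mean of probe sets), and Xbp1 was called with the intensity trend and without the dimmest 50%. Detection calls were not used here, so dim genes were not separated from undetected ones.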

Other observations

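The gene lists of this part and their tests were chosen after the gene values had been seen, and the genes named from them lie outside the naming rule. Of 44 lysosomal genes, 12 were called lower in the knockout and none higher, and 39 were negative. The list had a median of -0.21 (camera adjusted p = 6.9e-21, and adjusted p = 0.037 with an estimated correlation, over 7 such lists). Since these 7 lists were chosen from the values, their list tests are not separate support for the shifts. They were not adjusted together with the 37 fixed lists, whose lowest adjusted p was 0.16 by camera with an estimated correlation. The genes called lower included the ganglioside activator gene Gm2a (-0.75 ± 0.079, SE), the cathepsin genes Ctss (-0.69 ± 0.080), Ctsl (-0.39 ± 0.059) and Ctsd (-0.34 ± 0.057), the hydrolase genes Man2b1 (-0.51 ± 0.068) and Gla (-0.42 ± 0.055), and the membrane protein gene Lamp2 (-0.38 ± 0.063). Ctsk (0.33) and Smpd1 (0.20) differed upward and were not called.

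Of 23 coat genes of the vesicles that run between ER and Golgi, 11 were called higher and none lower, at a median of 0.31 (camera adjusted p = 5.8e-17, and adjusted p = 0.056 with an estimated correlation). Cope rose by 0.57 ± 0.066 (SE), Copb2 by 0.47 ± 0.062, Copa by 0.37 ± 0.055 and the COPII gene Sec13 by 0.33 ± 0.056. Among laminin and hemidesmosome genes, which anchor epithelium to its basement membrane, 3 of 12 fell, Lama3 (-0.70 ± 0.13), Lamb3 (-0.64 ± 0.070) and Lamb2 (-0.39 ± 0.073), at a list median of -0.092 (camera adjusted p = 7.9e-05, and adjusted p = 0.056 with an estimated correlation). Of the metallothionein genes, Mt1 changed by 1.87 ± 0.058 and Mt2 by 0.26 ± 0.27 (adjusted p = 0.75), a difference of 1.61 ± 0.38 (SE) within arrays. Mt2 scattered among the knockout arrays (SD 0.66, against 0.10 in wild type), so it was not shown to be unchanged. The zinc importer gene Slc39a4 fell by 0.37 ± 0.068 on the log2 scale. The list of zinc and metallothionein genes did not pass camera (adjusted p = 0.57) but passed fry (adjusted p = 0.0015), with 5 of 10 members positive. Of imprinted genes outside the Meg3 cluster, Grb10 rose by 0.82 ± 0.11, and their list did not pass camera (adjusted p = 0.14) or fry (adjusted p = 0.13).

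Wild type array 3 stood apart from the other wild type arrays toward the knockout in the PERK-ATF4-CHOP targets, where its mean deviation was 0.20, against -0.14 and -0.07 in the other wild type arrays and 0.73 to 0.75 in the knockout. Among them it read 7.63 for Slc7a11 against 6.02 and 6.48, 8.57 for Chac1 against 7.20 and 7.07, and 10.25 for Asns against 9.72 and 9.81, and outside them 9.77 for Pnliprp2 against 6.25 and 7.34. Of these, limma called Slc7a11 and Asns.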
